A study of Mycosarcoma maydis with 2 samples.

How the data were processed

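RNA was measured by sequencing in the corn smut fungus Ustilago maydis (now Mycosarcoma maydis), grown in liquid minimal medium with glucose or with ethanol as the carbon source. Per the labels, cells were grown for 24 h in complete medium with 1% glucose, moved to minimal medium with 1% of either carbon source and collected after 14 h. Per the series' design text, 3 biological replicates per treatment were pooled before sequencing, so each group is 1 library and the spread between cultures cannot be measured.

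Per the submitters' processing notes, reads were trimmed with Trimmomatic 0.36 and transcript abundance was estimated with kallisto. The kallisto version, its index options, the strandedness of the libraries and the read layout are not given in the sources used here. Per the file headers, the deposited tables give for each transcript model its length, effective length, estimated count and TPM. The deposited estimated counts are not normalized, and a read that fits several models is divided between them, so some values are not whole. The deposited TPM values are the estimated counts divided by effective length and scaled to 1000000 per library. The target names in the files carry the transcript set name Ustma2_2. Both libraries list the same 6785 models at 6767 loci, and 18 loci have 2 models each. Of the model lengths, 99.8% are multiples of 3, so lengths are read as coding lengths and untranslated regions are not covered.

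Locus tags were looked up in the RefSeq gene table of assembly Umaydis521_2.0, where 6780 models matched and 5 did not. That table gives a symbol other than the locus tag for 15 of the loci and describes no gene product. The build behind the transcript set is not given in the sources used here, so the table served only for symbols, chromosome membership and gene order, and no coordinates are printed. The 34 gene lists fixed before the data were examined (carbon metabolism, mitochondrial function, ribosomes, stress, cell wall, mating, signalling, cytoskeleton and others) were defined by words in symbols or product names. None of them found a member here, so no list was scored and the alternatives planned for list medians and percentiles were not run. For the same reason, the planned rule of naming the 12 highest and the 12 lowest genes with an informative product named none. The text names instead the 2 models with the highest and the 2 with the lowest ratio, the 5 models with the highest TPM in each library (planned), and the 15 loci with a symbol; runs of neighbouring genes were chosen after their values were seen.

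Estimated counts were rounded to whole numbers and scaled with the trimmed mean of M-values (TMM) of edgeR 4.0.16 in R 4.3.3. The log2 ratio of ethanol over glucose was taken from edgeR's logCPM values with a prior count of 2, and levels are TMM-scaled CPM (counts per 1000000 counts of effective library size). Ratios are summarised for the 6001 models (88.5%) with at least 50 counts in at least 1 library. Folds stated for single genes are ratios of scaled counts without a prior count (ranges over the genes of a run are of the fitted ratio), with exact (Clopper-Pearson) 95% intervals conditional on the 2 counts. Against a library with a count of 0, a lower bound was computed with 3 counts in that library. These intervals and bounds cover counting error only. With 1 library per group no test between the carbon sources was made, no p-value was computed, and counts of genes past 2-fold are counts by size. Rank correlations across models and correlations between neighbours describe these 2 libraries, and genes are not independent replicates. The 95% intervals of these correlations treat models or pairs as independent. They may therefore be too narrow, and they do not cover the spread between cultures.

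For gene order, the model with most counts was kept at each locus, and genes below the count minimum were skipped, so neighbours are neighbours among the 5982 measured genes on 23 chromosomes. Observed values were set beside 10000 random orders within chromosomes, 1000 of which were also used for runs. Gene groups were set beside 10000 random groups of the same size, matched on mean expression (scaled CPM, not corrected for length) in 20 bins. Python 3.11.15 with scipy 1.17.1 and pandas 2.3.3 was used. The alternatives were DESeq2 1.42.0 size factors, total counts, upper-quartile scaling, log2(TPM + 1), prior counts of 0.5 and 10, other count minimums, a 4-fold threshold and a threshold on the counting interval.

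The scripts were tested on simulated data with the real means and library sizes of all 6785 models, in which 200 models were changed by known folds. Counts were drawn with counting error only, at the TMM scaling of the real data. The changed models had an expected count of at least 50 before the change. The simulation therefore tests neither the choice of scaling nor any spread between cultures. For this comparison, the median recovered log2 ratio was 1.98 for 50 models simulated at 2 and -2.03 for 50 simulated at -2. For 50 models each simulated at 1 and -1, the medians were 1.00 and -1.01. Among 5698 unchanged models, 1 passed 2-fold by counting error and 95.4% had an interval that held the true ratio. Depth was 7446527 estimated counts in the glucose library and 7590138 in the ethanol library.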

Results

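Transcript abundance was compared between Ustilago maydis cultures grown for 14 h with 1% ethanol and with 1% glucose as the carbon source. U. maydis is a plant-pathogenic basidiomycete that grows either as a budding yeast or as a mycelium, and the series asks how ethanol brings about the change from yeast to mycelium. Each carbon source was represented by 1 library made from 3 pooled cultures. Every difference below is therefore a difference between 2 libraries with no replicate check. The glucose library held 7446527 estimated counts and the ethanol library 7590138, with medians of 275.0 and 329.0 counts per model. The 10 models with most counts took 20.3% of the counts in glucose and 20.8% in ethanol. In glucose, 170 models were listed at 0, against 69 in ethanol.

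Of the 6001 models above the count minimum, 400 (6.67%) were at least 2-fold higher in ethanol, 499 (8.32%) were at least 2-fold lower, and 5102 (85.0%) lay within 2-fold. At 4-fold, 62 models were higher and 107 were lower. The middle of the distribution lay at a log2 ratio of -0.0056, with quartiles of -0.41 and 0.40, and levels in both libraries correlated across models with Spearman's rho of 0.91. For 198 of the higher and 370 of the lower models, the whole 95% counting interval lay beyond 2-fold. The split between higher and lower depended on the scaling. With scaling by total counts the median ratio was higher by 0.27 on the log2 scale, and 737 models were at least 2-fold higher against 330 lower. With the deposited TPM values the counts were 996 and 227. Upper-quartile scaling also gave more higher than lower models, 561 and 387, whereas DESeq2 size factors gave 381 and 524.

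The 2 models with the largest fitted ratios in favour of ethanol were UMAG_03751 and UMAG_11416, whose order depends on the prior count. UMAG_03751 had log2 ratios of 5.08 with a prior count of 2 and 6.003 with 0.5, and UMAG_11416 had 4.74 and 6.70. UMAG_03751 was measured with 114 counts in ethanol and 1 in glucose, a 92.4-fold ratio with a 95% counting interval of 16.3 to 3681. UMAG_11416 had 57 counts in ethanol and 0 in glucose, which makes it at least 15.4-fold higher when 3 counts are taken as the limit in the glucose library; the exact 95% counting interval, which also covers the error of the 57 counts, starts at 12.1-fold. At the other end, UMAG_05812 had 111 scaled CPM in the glucose library and 1.20 in the ethanol library, and was 92.7-fold lower (95% counting interval 50.1 to 194). UMAG_04014T0 was 57.4-fold lower (47.9 to 69.4), at 825 and 14.4 scaled CPM. The second model of the same locus, UMAG_04014T1, had 2021 counts in glucose and 55 in ethanol, a log2 ratio of -5.45. Because both models of this locus share sequence, the division of reads between them is an estimate. Models without any count were more frequent in glucose. In all, 120 models had counts in the ethanol library and none in glucose, and 19 had counts in the glucose library and none in ethanol, with at most 57 and 12 counts.

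Among the most abundant transcripts, UMAG_00496 showed the largest difference. It was the model with the highest TPM in glucose, at 55184 TPM and 1.24% of all counts, and had 4557 TPM and 0.0871% of the counts in ethanol, where it ranked 27. On scaled counts it was 17.2-fold lower in ethanol (95% counting interval 16.8 to 17.7). UMAG_04974 was 2.84-fold lower (2.79 to 2.89), with 5740 scaled CPM in glucose and 2023 in ethanol, and its log2 ratio was -0.9996 with TPM. UMAG_12350 was 2.15-fold lower (2.05 to 2.25), but within 2-fold under scaling by total counts, where its log2 ratio was -0.83. Its model is 78 bases long with an effective length of 11.03 bases in glucose, so 0.0615% of the counts gave it 37963 TPM. UMAG_03881, the model with the highest TPM in ethanol, held 3.95% of the counts in glucose and 4.23% in ethanol. Its log2 ratio was -0.18 with TMM and 0.10 with scaling by total counts, so its direction was not settled. The other models among the 5 highest in either library, UMAG_11921, UMAG_11789 and UMAG_00082, had log2 ratios of -0.46, -0.37 and 0.06, all within 2-fold. Of these, UMAG_11921 and UMAG_11789 had TPM ratios of the opposite sign, 0.06 and 0.13.

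The 15 loci with a symbol belong to 4 families, and 8 of them were above the count minimum. They were named because they have a symbol and not for their values. In the opt family, which is named for oligopeptide transporters, 1 of 4 measured genes was at least 2-fold higher in ethanol and 3 lay within 2-fold. The former was opt4 (UMAG_02387), with 10 counts in glucose and 50 in ethanol, 4.05-fold higher (95% counting interval 2.03 to 8.96). The log2 ratio was 0.42 for opt1 (UMAG_10908), 0.58 for opt6 (UMAG_04347) and -0.55 for opt5 (UMAG_10896). The remaining members, opt2 and opt3, were below the minimum, with 1 and 21 counts in glucose and 0 and 45 in ethanol. In the dur3 family, named for urea transporters, dur3-1 (UMAG_02625) was 3.02-fold lower in ethanol (2.36 to 3.89), at 33.2 and 11.02 scaled CPM. The log2 ratio of dur3-1 was -0.97 with TPM. The more abundant dur3-3 (UMAG_04577) had 92.5 and 89.0 scaled CPM, a log2 ratio of -0.056 with TMM and 0.22 with scaling by total counts. The third member, dur3-2 (UMAG_06253), was below the minimum, with 21 counts in glucose and 41 in ethanol. In the egl family, named for endoglucanases that cut cellulose, egl1 (UMAG_06332) was 3.39-fold lower in ethanol (2.37 to 4.92), with 118 counts in glucose and 43 in ethanol. Its relatives egl2 and egl3 were below the minimum, with 10 and 9 counts in glucose and 35 and 8 in ethanol. In the afu family, afu2 (UMAG_00837) was 2.98-fold higher (2.14 to 4.22), at 6.80 scaled CPM in glucose and 20.2 in ethanol. The genes afu1 and afu3 were below the minimum, with 18 and 24 counts in glucose and 32 and 6 in ethanol.

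The ratio of ethanol over glucose was lower for abundant than for scarce transcripts. In the decile of models with the lowest mean level (601 models below 11.1 scaled CPM), 162 were at least 2-fold higher in ethanol and 44 were lower, with a median log2 ratio of 0.49. The scarcest models of this decile, down to 1.01 scaled CPM, passed the count minimum only by being high in 1 library. In the decile with the highest mean level (600 models above 256 scaled CPM), 13 were higher and 90 lower, with a median of -0.36. The median was lower in each successive decile, and Spearman's rho between the log2 ratio and the mean level was -0.31 across models. Scaling by total counts moved the medians of the lowest and the highest decile to 0.75 and -0.081, with 229 models higher and 31 lower in the lowest decile and 23 higher and 50 lower in the highest. With total counts the highest decile alone had a median below 0, whereas with TMM the 5 highest deciles did.

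**Figure D1:**
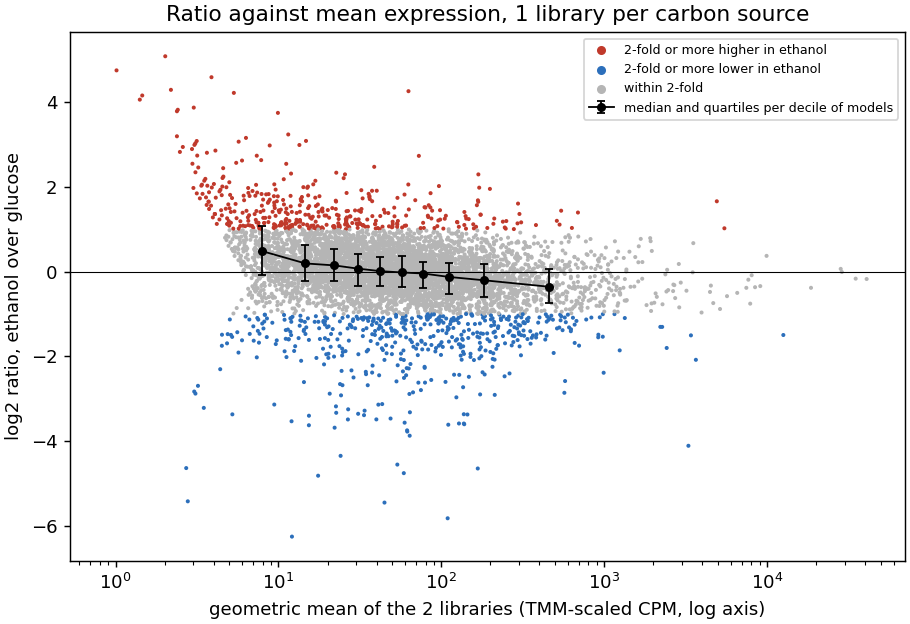
The log2 ratio of ethanol over glucose (vertical axis) is plotted against the geometric mean of the 2 libraries in TMM-scaled CPM (horizontal log axis), with 1 point for each of the 6001 models above the count minimum and with black points and bars for the median and quartiles of each decile of models. The 400 models at least 2-fold higher are red and the 499 at least 2-fold lower are blue, and the medians run from 0.49 in the lowest decile to -0.36 in the highest.

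Some genes with large ratios lay in runs along the chromosomes: 116 (12.9%) of the 897 measured genes past 2-fold were in runs of 3 or more neighbours with the same direction. The longest run held 7 neighbouring genes from UMAG_04082 to UMAG_11528, each at least 2.73-fold higher in ethanol on the fitted ratio, with a median log2 ratio of 1.68 and a summed 775 counts in glucose against 3215 in ethanol. Within it, UMAG_04086 was 10.05-fold higher (95% counting interval 4.08 to 32.0) and UMAG_04087 was 10.03-fold higher (6.61 to 15.9). The run was parted by a single gene, UMAG_04081 (log2 ratio -0.020), from a run of 4 genes in the other direction, UMAG_04076 to UMAG_04080, which were 2.48-fold to 3.69-fold lower on the fitted ratio. A second run of 5 genes, UMAG_02245 to UMAG_10082, was 2.04-fold to 2.82-fold higher in ethanol on the same scale. The longest run of lower genes held 5 genes from UMAG_02508 to UMAG_02512, with 52835 counts in glucose and 15609 in ethanol and a median log2 ratio of -2.08. A lower run as long occurred in 23 of 1000 random orders. The longest lower run held 4 genes with total counts or upper-quartile scaling, 3 with TPM and 6 with DESeq2 size factors. These runs were singled out after their values were seen.

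**Figure D2:**
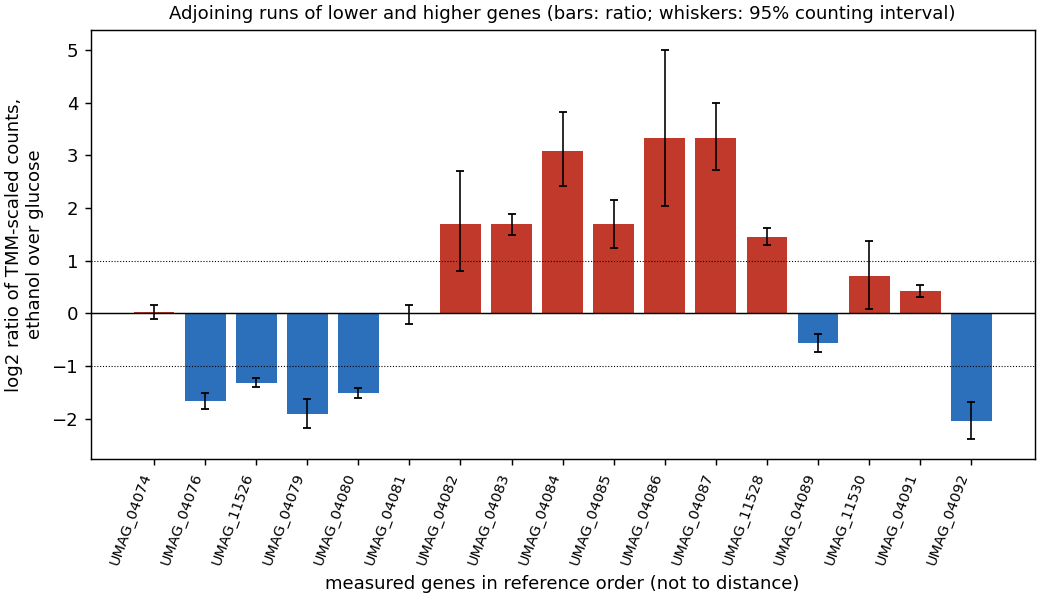
Bars give the log2 ratio of TMM-scaled counts, ethanol over glucose, for measured genes in their order on the chromosome (horizontal axis, not to distance), and whiskers give the 95% counting interval. The 4 genes from UMAG_04076 to UMAG_04080 lie below -1, UMAG_04081 lies near 0, and the 7 genes from UMAG_04082 to UMAG_11528 lie above 1, although the interval of UMAG_04082 reaches below 1.

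Counted over the genome, 13 runs of 3 or more neighbours were at least 2-fold higher throughout and 20 were at least 2-fold lower throughout. In 1000 random orders within chromosomes the median numbers were 1 and 3 and the highest were 7 and 9. The log2 ratios of direct neighbours correlated with a Pearson's r of 0.17 over 5959 pairs, and r was 0.070 at a distance of 2 genes and 0.0090 at 3. The central 95% of random orders gave between -0.025 and 0.026 for direct neighbours. The numbers of runs followed the scaling, at 33 and 13 with total counts and 54 and 5 with TPM. Runs in random orders were counted for TMM ratios only, so the numbers under other scalings have no random counterpart here. The median log2 ratios of the 23 whole chromosomes lay between -0.12 and 0.057.

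**Figure D3:**
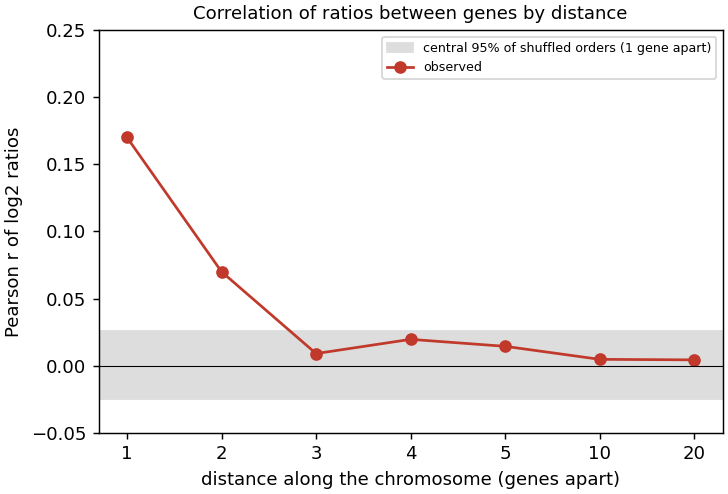
Pearson's r of the log2 ratios of 2 genes (vertical axis) is plotted against their distance in measured genes along the chromosome (horizontal axis), and the grey band holds the central 95% of random orders for direct neighbours. The value is 0.17 for direct neighbours, 0.070 at 2 genes and within the band from 3 genes on.

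Genes at the chromosome ends differed more often than others. Of the 351 measured genes among the outermost 10 loci at each end, 26.5% were at least 2-fold higher or lower, against 14.3% of the other genes. These 351 were 76.3% of the 460 end loci, whereas 89.5% of the 6295 other loci passed the count minimum. Random groups matched on mean expression gave 17.1%, with a central 95% from 13.7% to 20.8%. They were drawn as single genes, whereas end genes adjoin and the ratios of neighbours correlated, so these ranges may be too narrow. The comparison of chromosome ends was not among the planned ones. Genes higher in ethanol made up 56 of the 351 (15.95%) against 9.12% in matched groups (central 95% 6.27% to 11.7%). Genes lower in ethanol made up 37 (10.5%), inside the central 95% of matched groups (5.41% to 11.1%). With total counts, 23.1% were higher against 15.4% in matched groups (12.3% to 19.1%), and 7.69% were lower against 5.41% (3.42% to 7.98%). With TPM, both the higher genes (27.6% against 19.4%, 15.7% to 23.4%) and the lower genes (6.84% against 3.70%, 1.99% to 5.70%) lay above the matched groups.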

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

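The alternatives for the correlation between neighbours, the trend with mean level, the named runs, the chromosome ends and the shortest models were chosen after seeing the data; the others were planned. The counts of higher and lower models depended on the scaling, the count of higher models also depended on the count minimum, and there are no replicates from which to choose a scaling. Against 400 higher and 499 lower models, total counts gave 737 and 330, TPM gave 996 and 227, and a 4-fold threshold gave 62 and 107. The number higher was 639 without a count minimum, 202 with a minimum of 200, 226 with a minimum of 50 in both libraries, and 198 when the whole counting interval had to pass 2-fold. Under the same 4 settings the number lower was 552, 420, 450 and 370. The median over models, -0.0056, became -0.024 with DESeq2 size factors, 0.27 with total counts, 0.15 with upper-quartile scaling, 0.45 with TPM, 0.033 without a minimum, -0.066 with a minimum of 200 and -0.039 with a minimum of 50 in both libraries. With these last 3 minimums, the correlation between neighbours was 0.22, 0.13 and 0.13, and the trend with mean level was -0.34, -0.27 and -0.24. With TPM the trend was -0.27. A scaling that shifts every log2 ratio alike cannot change these 2 correlations. DESeq2 size factors, upper-quartile scaling and both other prior counts left the counts of higher and lower models within 1.5 times. Of these, upper-quartile scaling nevertheless turned the majority, with 561 models higher and 387 lower. For the 26 named models, 116 of 156 alternative values lay within the counting interval, 40 lay outside it, and no model past 2-fold changed direction. The medians of the 4 named runs kept their sign in all 6 alternatives run. Leaving out a replicate and a paired fit had nothing to act on, because each carbon source has 1 library. Depth limits the scarce models: with 1 count in glucose, the interval of UMAG_03751 spans 16.3-fold to 3681-fold.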

Other observations

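The tests of explanations below were chosen after the patterns were seen, apart from the one on the count minimum and the one on the number of libraries, whose results had not been seen. Short models had lower ratios of ethanol over glucose than other models of like scaled count. Groups were matched on counts not corrected for length, so at a like count a short model had the higher TPM. Whether a trend with TPM level accounts for the difference was not tested. In the shortest decile of models (601 models of 78 to 543 bases), 103 were at least 2-fold lower in ethanol and 33 were higher, with a median log2 ratio of -0.16; with total counts 70 were lower and 62 higher, and the median turned to 0.12. None of 10000 random groups matched on mean expression had a median as low, and their central 95% ran from -0.048 to 0.063. Total counts shift the decile and its matched groups alike and so cannot test this difference. With TPM the median was 0.34, below every matched group (central 95% 0.41 to 0.52). In the longest decile, 22 models were lower and 30 higher, or 12 and 58 with total counts.

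At the 10 loci where both transcript models passed the count minimum, the models had ratios of the same sign in 8. The largest difference was at UMAG_03726, singled out for it, where the first model had a log2 ratio of -2.39 and the second -0.80. The first model there took 94.8% of the locus's counts in glucose and 85.9% in ethanol. The 34 models shorter than 200 bases held 0.871% of the counts and 14.5% of the TPM in glucose, and 0.685% and 12.7% in ethanol.

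The ratio of ethanol over glucose declined with mean level (rho = -0.31), while the direction of the abundant models depended on the scaling. A count minimum that admits scarce models which are high in 1 library does not account for the trend above 11.1 scaled CPM. Every model passes the minimum there, and rho was -0.26 among these 5400 models. In the lowest decile, where the minimum acts, its part in the trend stays open. With a minimum of 50 counts in both libraries, 226 models were at least 2-fold higher and 450 lower, and rho was -0.24. A uniform background of reads in the ethanol library does not account for the trend among the more abundant 5 deciles of models, where rho was -0.19 (95% interval across models -0.22 to -0.15). For the scarce models it stays open: 2.80% of the 4639 models of at least 1 kb had an ethanol read density below 0.5 of the background that would be needed, between the bounds set for and against it. The carbon source and any other difference between the 2 libraries cannot be told apart with 1 library per group, so a broad response to ethanol is a hypothesis only.

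Neighbouring genes shared their direction (r = 0.17). None of 10000 random orders within chromosomes reached this value (0 orders; the highest was 0.051), which argues against chance order. Leaving out every model with a fractional count left r at 0.18 (95% interval 0.15 to 0.20), which argues against reads shared between models. Run-through of transcripts from an abundant gene into a scarce neighbour would, as the only cause, leave little correlation in pairs of like level. In 2012 pairs whose mean levels lay within 2-fold, r was 0.22 (0.17 to 0.26), so the correlation was not confined to pairs of unlike level. Pairs chosen for like level leave out an abundant gene beside a scarce one. They therefore cannot test whether such run-through occurs where it would act. Levels here were scaled CPM, not corrected for length. In 1126 pairs that differed by 8-fold or more, r was 0.058. Without the trend with mean level, r was 0.17 (0.13 to 0.22) in the like pairs and 0.15 (0.094 to 0.21) in the unlike pairs. Regulation shared by adjacent genes was not tested and is a hypothesis only. Run-through between genes of equal level stays open, as does run-through from the abundant gene in pairs of unlike level. Any cause that the carbon source shares with other differences between the libraries also stays open. The value did not rest on the longest runs alone, since without the 53 genes in the 12 runs of 4 or more it was 0.14.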
